A study of Mus musculus with 30 samples.

How the data were processed

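Mouse embryonic stem (ES) cells of strain 129/Ola were grown in serum medium with LIF, per the labels' protocols. Esrrb ChIP-seq libraries were made with a low-input kit (Diagenode MicroPlex) from asynchronous and mitotic cells, and RNA-seq libraries with a stranded mRNA kit (Illumina TruSeq) from cells sorted by a Ccna2-Gfp reporter. The RNA-seq came from EKOiE cells that carry that reporter, an Esrrb knockout line with a DOX-inducible Esrrb transgene. The ChIP-seq came from EKOiE, except for replicate 2 of both DOX groups, which came from wild-type E14Tg2a. The ChIP-seq groups held 4 interphase and 4 mitosis libraries with DOX and 2 libraries of each after 48 h of withdrawal. The RNA-seq groups held 3 libraries for each of early G1, late G1 and G2, with DOX and after 24 h of withdrawal. The labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between samples.

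The submitters' processing notes name build mm9, CASAVA 1.8, Bowtie and DESeq2, with no role or order for any of them. The deposited exonic and intronic tables hold raw counts per RefSeq transcript over exons and over introns, per the file headers. The counting tool, the annotation version and the strand setting are not given in the sources used here, so that overlapping and antisense genes and near-identical families, such as the replication histones, are uncertain as single genes. Exons are given for 20300 genes and introns for 17916, the latter followed by 2377 blank lines. In both, 27 symbols had been turned into calendar dates, and all 27 were restored through their RefSeq accessions with a reference table of assembly GRCm38, used for names alone.

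The deposited peak table gives 14559 Esrrb peaks in mm9 with a height per library and per pooled group in log2 reads per kb of peak per mega (M) reads, written with a decimal comma. The unit was read from the values: within each library, 2 to the power of the value, times the peak length, is a whole multiple of 1 step (tolerance 0.05 read), and an empty peak is set to 0.9 read. Reads per peak and library totals were recovered from this step. Peak widths run from 300 to 6750 bp in steps of 150 bp. Columns headed noco were taken as the mitosis libraries of the same number, a word the labels do not use. The authors sort the peaks into 5 classes, of which classes 1 to 3 are called Bookmarked (1980 peaks) and classes 4 and 5 Lost (12579 peaks), per the file headers. How peaks were called and classes set is not given in the sources used here. The planned design allowed for counts or a gene assignment in this table. It holds normalised log2 values and no gene, so limma was used for the heights, and each peak was assigned here to the nearest transcription start in the exonic table (mm9) within 50 kb.

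The comparisons, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined, apart from those said to be added later. The 18 RNA-seq libraries entered 1 edgeR fit (edgeR 4.0.16, R 4.3.3) of 6 group means, with filterByExpr at its default settings, TMM scaling, quasi-likelihood F tests and Benjamini-Hochberg (BH) adjustment at 0.05. This left 14092 exonic and 14075 intronic genes and 12 residual degrees of freedom. The SE of a log2 change is its absolute value divided by the square root of the F statistic. Contrasts were withdrawn minus DOX in each phase, pairs of phases with DOX, and the differences in response between phases. Counts summed over the 3 phases per replicate and DOX state were added after the data were seen. The biological coefficient of variation was 0.187 for exons and 0.188 for introns, and 0.115 and 0.124 with the replicate number as a block. ChIP-seq heights entered 1 limma fit (limma 3.58.1, trend) of 4 groups. CPM values are TMM-scaled. Principal components used the 2000 most variable genes. For called genes with at most 3 counts in a group, the ratio of counts is given with a 95% exact binomial interval on effective library sizes, added after the data were seen.

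Gene lists were tested with camera at a preset correlation of 0.01 and BH adjustment over the 19 lists of each contrast. An estimated correlation and fry, which asks whether a list's own genes move one way and compares it with no other gene, were the alternatives. The 19 lists cover naive and core pluripotency, formative and primed cells, primitive endoderm, mesendoderm, neural, trophoblast, 2-cell-like and fibroblast or feeder cells, G1/S and replication, G2/M, replication histones, immediate-early and stress genes, targets of LIF and STAT3, Wnt, FGF and ERK, and p53, oxidative metabolism under ERR receptors, and glycolysis. A list of ATF4 stress-response genes was added after the data were seen and is adjusted apart. Falls and rises of genes beside peaks were compared with Fisher's exact test, 2-sided, over the genes tested, and with 10000 lists drawn in 20 bins of expression or of peak height. Percentages of reads in peaks were compared by exact permutation tests.

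Named genes are Esrrb and Ccna2, and, per phase of withdrawal, the 10 largest falls and 10 largest rises past 0.05 with a mean log2 CPM of at least 2 and no overlap between the groups. The numbers were 8 for pairs of phases and 5 for introns, and up to 4 members past 0.05 were taken from each list. Named peaks are the 10 highest in mitosis by the authors' pooled height and those nearest to naive pluripotency genes or Esrrb.

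Replicate numbers are shared between groups. Deviations from the group means of same-numbered exonic libraries correlated at 0.11 or above in every pair of groups compared, so the numbers were taken to pair the RNA-seq libraries. The lowest intronic value was 0.09, for replicate 2 in early G1, and the intronic tables come from the same libraries. Blocked values stand beside a count of genes or a list test where they change it. Calls of single list members are those without the block unless said. Several members that passed only with it are given under other observations.

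Alternatives were DESeq2 1.42.0, size factors of the RLE kind, library totals alone, no low-count filter, a stricter filter (CPM of 1 in 3 libraries and a total of 100), the replicate block, the compared groups alone and each library left out in turn. For peaks they were a pseudocount of 1 or 0.1, a threshold of 0.01, the higher part of the peaks, the fit without E14Tg2a, and a distance of 10 kb. Fits of recovered reads, cell line as a term and peaks at any distance were added after the data were seen. So were list tests with the replicate block and comparisons of genes beside peaks that use block calls. The overlap that makes peaks shared was not varied, since the table gives 1 merged set.

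The gene fits were first tested on simulated data for withdrawal in early G1 and for G2 minus early G1, and the peak fit for mitosis minus interphase; the list tests, Fisher's tests and matched lists were not. Of 67 simulated exonic genes changed 1.5-fold in early G1, 17.9% were recovered, 65.7% at 2-fold and 86.4% at 4-fold of 66, with 5 false calls among 13958 genes in the step. For introns the same shares were 9, 49.3 and 90.9% (13950 genes). Unlike the real RNA-seq libraries, the simulated ones shared no effect by replicate number, so that these shares may not hold for the real fits. For peaks lowered by 1, 2 and 3 log2 units, 23, 72.3 and 92.7% were recovered, with 153 false calls among 7281 unchanged peaks.

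Intronic totals for replicates 1, 2 and 3 were 10.3, 8.2 and 9.3 M in early G1 with DOX and 10.8, 9.1 and 13.3 M after withdrawal. They were 9.5, 8.4 and 8.8, then 9.7, 10.6 and 11.1 M in late G1, and 10.4, 6.1 and 9.3, then 20.8, 8.8 and 10.7 M in G2. The 10 highest genes took 6.3 to 8.8% of exonic and 19.9 to 39.9% of intronic counts per library. ChIP-seq libraries held 57392 to 2336956 reads in peaks, with a median of 2 to 116 reads per peak. The pooled heights of the peak table were used to name peaks, to match lists on peak height and to pick the higher part of the peaks. They were not themselves the values tested.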

Results

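Esrrb, an orphan nuclear receptor that binds DNA together with the pluripotency network of mouse embryonic stem (ES) cells, was measured in 2 ways in 30 libraries. The first was ChIP-seq of Esrrb (12 libraries) in asynchronous cells, called interphase here, and in mitotic cells collected by shake-off. The second was stranded mRNA-seq (18 libraries) of cells sorted into early G1, late G1 and G2 with a Ccna2-Gfp reporter, counted separately over exons and introns. The main line, EKOiE, is an Esrrb knockout ES line that carries a doxycycline (DOX)-inducible Esrrb transgene, so that DOX withdrawal serves to lower Esrrb. E14Tg2a is a wild-type ES line and gave replicate 2 of both DOX groups of the ChIP-seq. DOX was withdrawn for 24 h before RNA-seq and 48 h before ChIP-seq. Each of the 6 RNA-seq groups held 3 libraries. The ChIP-seq held 4 interphase and 4 mitosis libraries with DOX, and 2 withdrawal libraries in each state.

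Exonic totals ran from 11.1 to 31.8 M counts per library (M, mega) and intronic totals from 6.1 to 20.8 M. The exonic totals of replicates 1, 2 and 3 were 12.1, 11.4 and 18.6 M in early G1 with DOX and 17.9, 18.2 and 24.3 M after withdrawal. They were 15.1, 11.8 and 16.8 M in late G1 with DOX and 16.6, 17.8 and 21.0 M after withdrawal. In G2 they were 16.7, 11.1 and 18.8 M with DOX and 31.8, 17.7 and 20 M after withdrawal. The ChIP-seq libraries of the inducible and wild-type lines held 58.6, 38.2, 36.5 and 10.7 M reads in interphase with DOX and 54.6, 67.5, 49.7 and 33.9 M in mitosis with DOX. The withdrawal libraries held 26.6 and 40.5 M reads in interphase and 18.6 and 56.7 M in mitosis. Below, log2 values are withdrawn minus DOX unless another order is named, ± is the standard error (SE) for log2 changes and the standard deviation (SD) for group means, and n = 3 per RNA-seq group.

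The withdrawn gene and the reporter gene were read first. Exonic Esrrb counts per M (CPM) went from 243 ± 37.7 to 163 ± 27.3 in early G1, from 317 ± 28 to 165 ± 7 in late G1 and from 273 ± 26.9 to 190 ± 6.43 in G2 (SD, n = 3). Esrrb fell by 0.94 ± 0.14 on the log2 scale in late G1 (edgeR adjusted p = 0.00385). Its log2 changes of -0.58 ± 0.13 in early G1 and -0.52 ± 0.13 in G2 did not pass (edgeR adjusted p = 0.12 and 0.0699). With the replicate number as a block, Esrrb passed in all 3 phases (edgeR adjusted p = 0.0138, 0.000395 and 0.0123). In introns the Esrrb changes were -0.11, -0.14 and -0.12 and none passed. Reads of the transgene and of the knocked-out locus cannot be separated in the counts. Ccna2, the cyclin whose reporter drove the sort, stood at 313 ± 56.5 CPM in early G1, 347 ± 57.8 in late G1 and 424 ± 37.1 in G2 with DOX, and at 329 ± 52.4, 370 ± 11.5 and 434 ± 76.3 after withdrawal. Its G2 minus early G1 difference with DOX, 0.44 ± 0.16 log2, did not pass over all genes (edgeR adjusted p = 1).

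**Figure D1:**
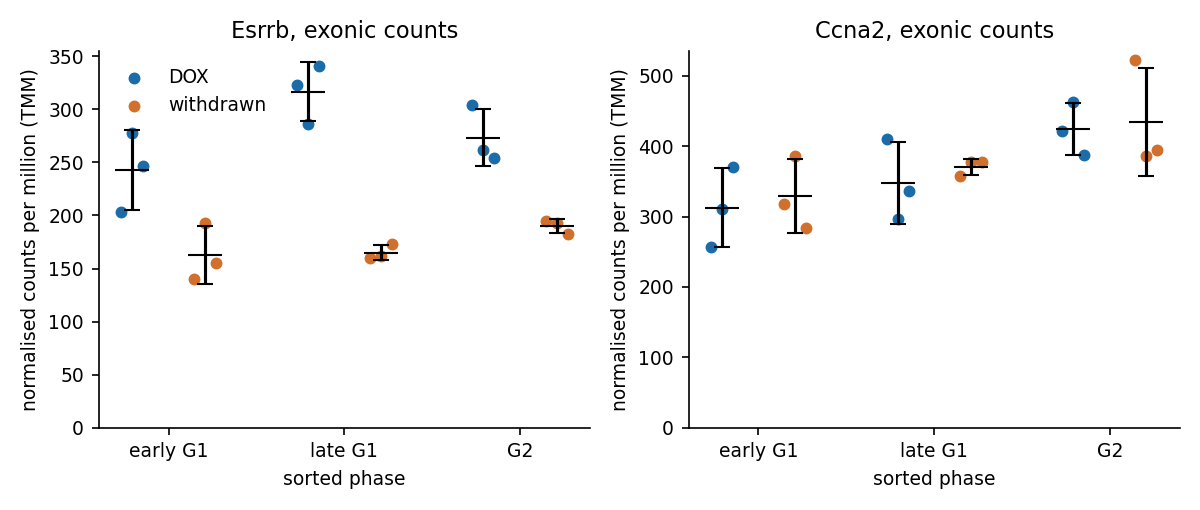
Normalised exonic counts per M (TMM) of Esrrb (left) and Ccna2 (right) in each library of the 3 sorted phases, with DOX and after 24 h of withdrawal; points are libraries, bars the mean and SD of 3. In each phase the withdrawn libraries lie below the DOX libraries for Esrrb, while Ccna2 libraries of the 2 states overlap.

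The first question was which genes respond when DOX is withdrawn, in each phase. In early G1, 17 genes fell and 6 rose of 14092 tested. The fallers included Tfcp2l1 (-0.90 ± 0.16, from 256 to 138 CPM; edgeR adjusted p = 0.0394), a transcription factor of the naive ES-cell state, and Jam2 (-0.96 ± 0.18; edgeR adjusted p = 0.0434), a junctional adhesion molecule. The metabolic gene Ldhb, which encodes a lactate dehydrogenase subunit, fell by 1.12 ± 0.13 from 224 to 103 CPM (edgeR adjusted p = 0.000871). At a mean log2 CPM of at least 2, the largest fall was that of Kdelr3 (-1.99 ± 0.26; edgeR adjusted p = 0.00196), a receptor that returns proteins to the endoplasmic reticulum, followed by Ly6g6e at -1.50 ± 0.17 (edgeR adjusted p = 0.000536). The largest rise was that of Ccnd2, the G1 cyclin D2 (1.87 ± 0.31, from 5.73 to 21.1 CPM; edgeR adjusted p = 0.0245). Lrrk1 (1.73 ± 0.26), Mtap7d3 (1.27 ± 0.22), Epas1 (1.26 ± 0.22), a hypoxia-inducible factor subunit, Pcyt1b (0.77 ± 0.13) and Qser1 (0.69 ± 0.12) were the other rises. Lrrc34 (-1.29 ± 0.24), Wfdc2 (-1.06 ± 0.20), Ppp2r2c (-1.01 ± 0.19), Ncs1 (-0.81 ± 0.15) and Calb2 (-0.80 ± 0.15) completed the 10 largest falls at that level of expression. Below it, Pvalb, which encodes the calcium-binding protein parvalbumin and was named after its values were seen, went from 43 to 67 counts per library with DOX to 0 to 2 (edgeR adjusted p = 3.27e-06). The ratio of its scaled counts was 0.0127 (95% exact binomial interval 0.00259 to 0.0377, for counting error alone). In mm9 and as the files place them, Kdelr3 (NM_134090) lies on chromosome 15 at 79346837 to 79358169, Tfcp2l1 (NM_023755) on chromosome 1 at 120524521 to 120581745 and Ccnd2 (NM_009829) on chromosome 6 at 127075726 to 127101066.

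The replicate block raised the early G1 count to 310 falls and 258 rises, and DESeq2 called 129 genes. Leaving out 1 library left 7, 4 and 16 calls without DOX replicate 1, 2 and 3, and 7, 5 and 6 without withdrawn replicate 1, 2 and 3; a fit of the 6 early G1 libraries alone called 6.

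In late G1, 39 genes fell, Esrrb itself among them, and 26 rose. Kdelr3 (-2.08 ± 0.26), Ly6g6e (-1.52 ± 0.17), Ldhb (-1.13 ± 0.13) and Wfdc2 (-1.13 ± 0.21) fell again. They were joined among the largest falls at the same level of expression by Fabp3, a fatty-acid binding protein (-1.78 ± 0.38; edgeR adjusted p = 0.0464), Wnt7b, a Wnt ligand (-1.40 ± 0.20; edgeR adjusted p = 0.00385), and Pdk4, a kinase that restrains pyruvate oxidation (-1.23 ± 0.23; edgeR adjusted p = 0.0299). Klhdc7a (-1.69 ± 0.24), Pramel6 (-1.19 ± 0.25) and Trf, which encodes transferrin (-1.17 ± 0.20), also fell. Ccnd2 rose by 2.14 ± 0.31 log2 (edgeR adjusted p = 0.00417) and Epas1 by 1.55 ± 0.22 (edgeR adjusted p = 0.00385). Myc, the growth-promoting transcription factor, rose by 1.21 ± 0.26 from 7.25 to 16.8 CPM (edgeR adjusted p = 0.045). The other large rises were Lrrk1 (1.38 ± 0.26), Ak7 (1.22 ± 0.25), Mtap7d3 (1.09 ± 0.21), Sema4d (1.05 ± 0.22), Bcl6b (1.02 ± 0.21), Dhx9 (0.96 ± 0.19) and Lrch2 (0.96 ± 0.18). The replicate block gave 597 falls and 677 rises, and DESeq2 332 genes. Without DOX replicate 1, 2 and 3 the count was 11, 17 and 23, without withdrawn replicate 1, 2 and 3 it was 38, 18 and 16, and a fit of the 6 late G1 libraries alone called 2 genes.

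In G2, 89 genes fell and 48 rose. Kdelr3 (-2.26 ± 0.26; edgeR adjusted p = 0.000382), Fabp3 (-2.06 ± 0.39) and Ly6g6e (-1.74 ± 0.17; edgeR adjusted p = 7.25e-05) were the largest falls at that level. Tgm2, a transglutaminase (-1.49 ± 0.29), Ntn1, which encodes the guidance cue netrin-1 (-1.49 ± 0.32), Klhdc7a (-1.47 ± 0.24), Trf (-1.38 ± 0.20), Ppp2r2c (-1.38 ± 0.20), Dcaf12l1 (-1.36 ± 0.31) and Lrrc34 (-1.27 ± 0.24) came next. Ccnd2 rose by 2.38 ± 0.32 and Lrrk1 by 1.94 ± 0.26 (edgeR adjusted p = 0.00172 for both). The chromatin remodeller Chd7 (1.13 ± 0.15; edgeR adjusted p = 0.00172) and the transcription factor Foxp1 (1.14 ± 0.18; edgeR adjusted p = 0.0047) each rose from about 40 CPM, at 39.5 and 39.8, to 86.4 and 87.6. Aoah (1.42 ± 0.22), Myrf (1.30 ± 0.27), Gap43 (1.16 ± 0.23), Epas1 (1.16 ± 0.22), Ak7 (1.13 ± 0.25) and Sema4d (1.10 ± 0.22) were the remaining large rises. The replicate block gave 767 falls and 813 rises, and DESeq2 449 genes. The count was 35, 38 and 85 without DOX replicate 1, 2 and 3, and 21, 157 and 34 without withdrawn replicate 1, 2 and 3, and a fit of the 6 G2 libraries alone called 25 genes. G2 withdrawn replicate 1 stood apart from replicates 2 and 3: it lay at -28.7 and -29.8 on principal components 2 and 3 of exonic counts, against -8.8 and -13.3, then 1.9 and 4.4, and at -35.9 on component 1 of intronic counts, against 4.5 and 9.1.

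A shared set of genes passed in all 3 phases. Tfcp2l1, Jam2, Ldhb, Kdelr3, Ly6g6e, Wfdc2, Ppp2r2c, Calb2, Ddah2, Ass1 and Pvalb fell in each (11 genes), and Ccnd2, Epas1, Lrrk1, Mtap7d3, Pcyt1b and Qser1 rose in each (6 genes). Late G1 and G2 shared 31 falls and 20 rises, where independent lists of those sizes would share 0.246 and 0.0886. Early and late G1 shared 11 falls and 6 rises, against 0.047 and 0.0111. All 99 genes that fell in any phase and all 54 that rose in any had the same sign of change in the other phases. No library is shared between phases, but the numbers 1, 2 and 3 are. The difference in response between phases passed for 0 genes in each of the 3 pairs with edgeR, with the replicate block and with DESeq2. At an unadjusted p under 0.05 (edgeR without the block) it held for 36 genes for late against early G1, 64 for G2 against early G1 and 72 for G2 against late G1. Each was under 5% of the genes tested, in a fit that leaves out the pairing by replicate number. These unadjusted counts therefore do not decide whether the responses differ. With 0 genes past the threshold, unequal counts of calls are not shown to be unequal responses, nor are the responses shown to be equal.

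**Figure D2:**
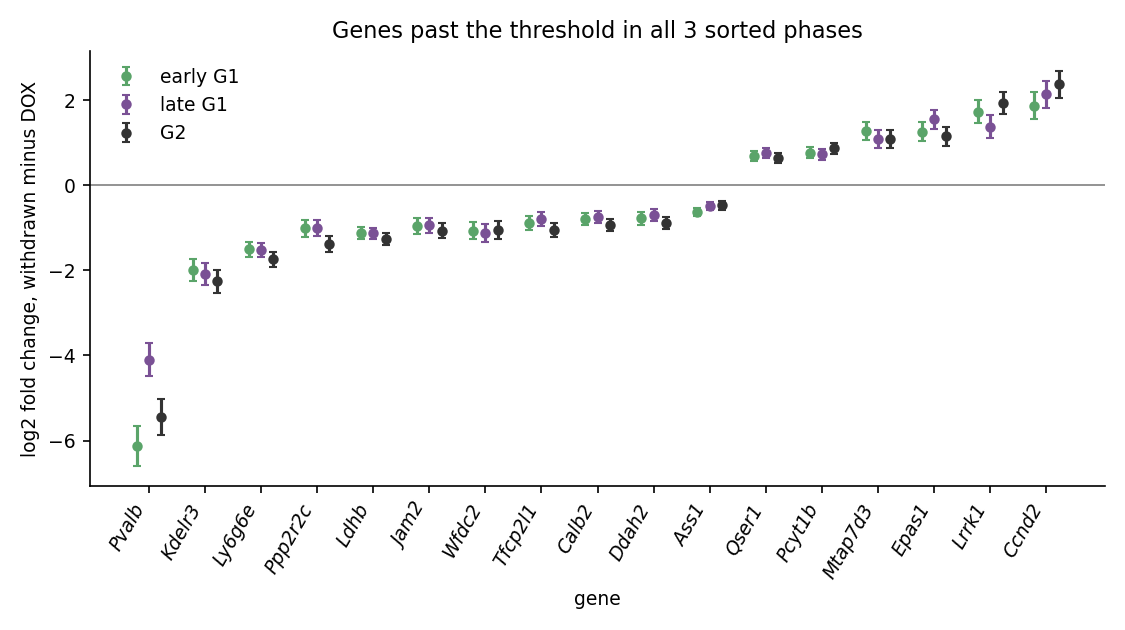
Log2 fold change, withdrawn minus DOX, of the 17 genes past the threshold in all 3 sorted phases; points are edgeR estimates per phase and bars the SE. Pvalb is lowest, with fitted values that rest on few withdrawn counts, Kdelr3 is next, near -2 in each phase, and Ccnd2 is highest, between 1.87 and 2.38.

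The fixed gene lists were used to ask whether markers of pluripotency and differentiation responded to withdrawal, singly or as sets. Of the 28 naive pluripotency genes, Tfcp2l1 and Jam2 fell in every phase and 0 rose, without the block. Adjusted over the list alone the counts were also 2 falls in each phase, with 1 rise in G2. With the replicate block Tbx3 fell in every phase too, and Dppa2 rose in late G1 and G2. In G2 the changes were -1.05 ± 0.16 for Tfcp2l1 (edgeR adjusted p = 0.0047) and -1.06 ± 0.18 for Jam2 (edgeR adjusted p = 0.00977). As a set the list did not pass (camera adjusted p = 0.0586, 0.205 and 0.312 for early G1, late G1 and G2), although it did in early G1 with the replicate block (camera adjusted p = 0.0277, and 0.597 with an estimated correlation). The 16 targets of LIF and STAT3, the signal that sustains ES cells, were lower as a set, with medians of -0.27, -0.25 and -0.20 (camera adjusted p = 0.000867, 0.00289 and 0.0322). With an estimated correlation the adjusted p was 0.0308, 0.0665 and 0.166, so that early G1 alone held. Among them 1, 2 and 2 genes fell and 0 rose; adjusted over the list alone 3, 3 and 2 fell. They were Tfcp2l1 in all phases and Pramel6 in late G1 (edgeR adjusted p = 0.0441) and G2 (-1.17 ± 0.25; edgeR adjusted p = 0.0263). In G2, leaving out 1 library ended that call in 3 of 6 fits, with a highest camera adjusted p of 0.0896 without DOX replicate 3.

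The 22 formative and primed genes, which rise as ES cells leave the naive state, were higher as a set, with medians of 0.30, 0.39 and 0.37 (camera adjusted p = 0.0084, 0.00213 and 0.00693). With an estimated correlation the adjusted p was 0.26, 0.119 and 0.166, and with the replicate block as well 0.0671, 0.0343 and 0.0363. Without the block no member passed over all genes. With it Dnmt3b and Lef1 rose in every phase, and Zic2 and Zic5 in late G1 and G2, as given under other observations. Adjusted over the list alone, without the block, 0, 4 and 5 rose and 0, 0 and 1 fell. Leaving out withdrawn replicate 3 ended the set's call in early G1 (camera adjusted p = 0.0812, the highest of 6 fits, of which 4 passed) and in G2 (0.0533, where 5 of 6 passed). The 18 core pluripotency genes, Pou5f1 and Sox2 among them, had medians of 0.10, 0.27 and 0.28 and passed as a set in G2 (camera adjusted p = 0.148, 0.0572 and 0.00935; adjusted p = 0.935 in G2 with an estimated correlation). They also passed in early and late G1 with the replicate block (camera adjusted p = 0.0489 and 0.00387, and adjusted p = 0.539 and 0.174 with an estimated correlation). The G2 call held in 3 of 6 fits that left out 1 library, with a highest camera adjusted p of 0.114 without DOX replicate 1.

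Of the 35 genes of oxidative metabolism that related ERR receptors control, Pdk4 fell in late G1 and in G2 (-0.97 ± 0.23; edgeR adjusted p = 0.0493), and adjusted over the list alone 1 fell in each phase. The set's median was -0.13, -0.08 and -0.09, and it passed in early G1 (camera adjusted p = 0.0184, 0.0966 and 0.249; adjusted p = 0.915 in early G1 with an estimated correlation); the early G1 call held in 4 of 6 fits, with a camera adjusted p of 0.6 without withdrawn replicate 3. Among 18 targets of FGF and ERK signalling, Spry4, a feedback inhibitor, rose in late G1 (0.76 ± 0.16; edgeR adjusted p = 0.0422) and G2 (0.82 ± 0.16; edgeR adjusted p = 0.0191) and Myc in late G1; adjusted over the list alone 1, 4 and 3 rose, and the set did not pass (camera adjusted p = 0.201, 0.086 and 0.0906). Among 21 immediate-early genes Fos fell in G2 (-1 ± 0.20; edgeR adjusted p = 0.0224) while Myc rose in late G1. That set did not pass (camera adjusted p = 0.516, 0.431 and 0.564) except in late G1 with the replicate block (0.0224, and 0.583 with an estimated correlation). Among 20 primitive endoderm genes the endocytic receptor Lrp2 rose in G2 (0.94 ± 0.18, from 255 to 489 CPM; edgeR adjusted p = 0.0191), without a call for the set (camera adjusted p = 0.961, 0.986 and 0.564).

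Without the block, no member of the other fixed lists passed over all genes in these contrasts. With it Lef1, also listed as a Wnt target, rose in every phase. The camera adjusted p in early G1, late G1 and G2 was 0.419, 0.986 and 0.729 for mesendoderm, 0.201, 0.986 and 0.516 for neural genes, 0.9, 0.233 and 0.0906 for trophoblast, 0.516, 0.613 and 0.715 for 2-cell-like genes, and 0.914, 0.852 and 0.876 for fibroblast and feeder markers. It was 0.419, 0.448 and 0.568 for Wnt targets, 0.201, 0.273 and 0.0906 for glycolysis, and 0.516, 0.448 and 0.516 for p53 targets. For the cell cycle it was 0.148, 0.0715 and 0.0906 for G1/S and replication genes, 0.419, 0.65 and 0.729 for G2/M genes, and 0.293, 0.548 and 0.984 for replication histones, whose near-identical copies make single genes uncertain. With the replicate block, G1/S genes passed in late G1 (0.0457) and glycolysis in G2 (0.0118), but neither held with an estimated correlation as well (adjusted p = 0.832 and 0.486).

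**Figure D3:**
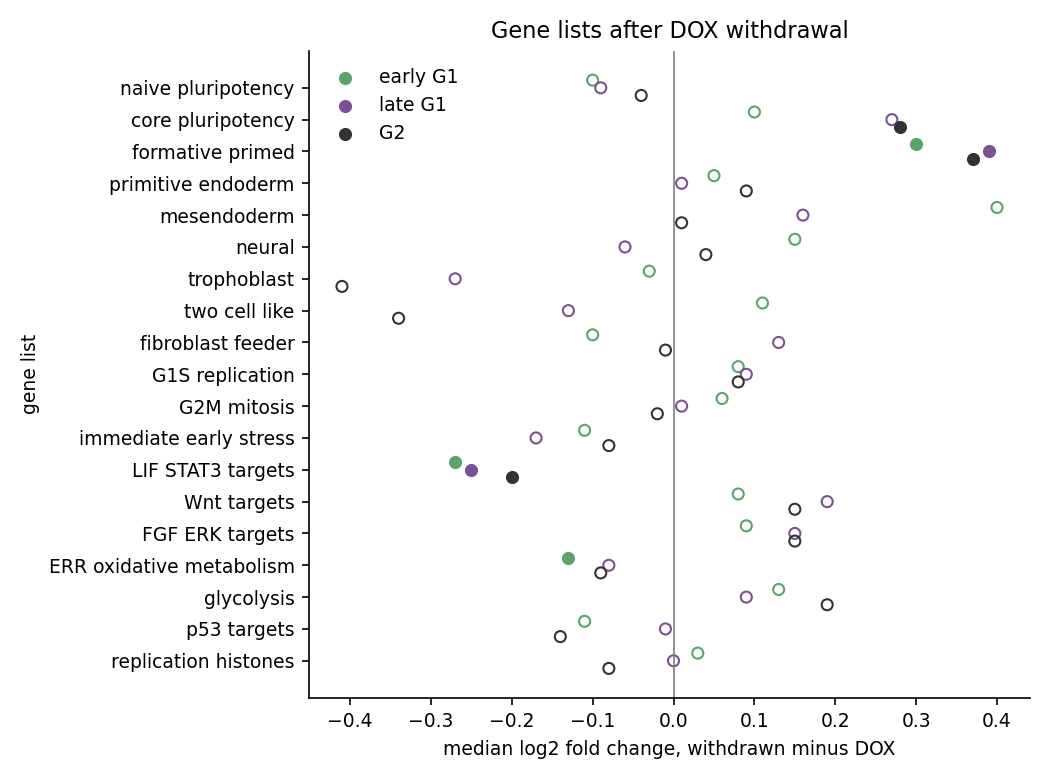
Median log2 fold change, withdrawn minus DOX, of the 19 fixed gene lists in each sorted phase (exonic counts); filled points have a camera adjusted p under 0.05. Formative and primed genes lie to the right and LIF and STAT3 targets to the left of 0 in all 3 phases.

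Intronic counts, which can reflect unspliced RNA, were used as an indirect reading of whether transcription itself responded. In every library the highest intronic gene was Tex14 or Filip1l, and the source of intronic reads was not tested. Wnt7b fell in late G1 (-1.29 ± 0.19; edgeR adjusted p = 0.0166) and Llgl2, a cell polarity gene, in G2 (-0.73 ± 0.11; edgeR adjusted p = 0.0211). The other intronic calls, in genes of lower counts and named after their values were seen, were Pvalb in late G1 (3 counts after withdrawal against 45 with DOX, a ratio of 0.0516 with a 95% exact binomial interval of 0.0103 to 0.161; edgeR adjusted p = 0.0166) and Fabp3 in G2 (-2.23 ± 0.33; edgeR adjusted p = 0.0211), which fell in exons too. In all, 0 genes passed in early G1, 2 in late G1 and 2 in G2 of 14075 tested with edgeR. The counts at an unadjusted p under 0.05 were 806, 820 and 1084, those with the replicate block 67, 89 and 228, and those of DESeq2 13, 15 and 41. Of the left-out libraries in late G1, DOX replicates 1 and 2 and withdrawn replicates 2 and 3 each left 0 calls, DOX replicate 3 left 1 and withdrawn replicate 1 left 2. In G2, 0 calls stayed without DOX replicate 1 or 2 or withdrawn replicate 1 or 3, 1 without DOX replicate 3 and 4 without withdrawn replicate 2. As sets, the intronic LIF and STAT3 targets (11 genes) had medians of -0.33, -0.38 and -0.17 (camera adjusted p = 0.000145, 0.00245 and 0.00533; adjusted p = 0.0153, 0.0417 and 0.0969 with an estimated correlation). Intronic immediate-early genes (13) had medians of -0.39, -0.42 and -0.42 (camera adjusted p = 7.14e-05, 0.00304 and 0.00273; adjusted p = 0.0527, 0.205 and 0.165 with an estimated correlation). Intronic ERR and oxidative genes (36) had medians of -0.18, -0.14 and -0.13 (camera adjusted p = 8.16e-06, 0.00245 and 0.00533; adjusted p = 0.0961, 0.402 and 0.579 with an estimated correlation). With 1 library left out, these calls held in all 6 fits per phase, except for immediate-early genes in late G1 (5 of 6; 0.0847 without withdrawn replicate 2) and ERR genes in late G1 (5 of 6; 0.0543 without withdrawn replicate 1) and G2 (4 of 6; highest 0.104, without DOX replicate 2). Introns made up 46 and 42% of counts in early G1 DOX replicates 1 and 2 and 41.7% in late G1 DOX replicate 2, against 33.3 to 39.6% in the other libraries. The 10 highest genes took 39.9, 35.2 and 35.1% of their intronic counts, against 19.9 to 33.9%. The fits left out 1 library at a time, so that an effect of this make-up on the early G1 falls is not excluded. These medians are relative to TMM scaling; library totals alone would move the median of all intronic changes by 0.383 in early G1 and 0.14 in late G1.

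Genes that fell or rose in exons mostly moved the same way in introns. Of the exonic falls measured in both tables, 14 of 16 in early G1, 36 of 36 in late G1 and 63 of 79 in G2 were below 0 in introns; of the rises, 6 of 6, 24 of 25 and 44 of 47 were above 0. Across 12516 genes, which are not independent replicates, Pearson's r between exonic and intronic changes was 0.35, 0.41 and 0.33 (Spearman's 0.34, 0.39 and 0.31). Both tables come from the same libraries and share chance values. Other splits of the same 6 libraries reached r up to 0.25, 0.32 and 0.20, against 0.37, 0.42 and 0.36 for the real split in the same fits. Over the 9113 genes with a mean log2 CPM of at least 2 in both tables, other splits reached 0.30, 0.42 and 0.29, against 0.39, 0.44 and 0.36. The other splits used for these correlations swapped the DOX state within a single same-numbered pair. They are too few to exclude chance, and each keeps part of the withdrawal difference, so that these gaps decide nothing.

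The second question was how the sorted phases differ in cells with DOX. G2/M genes, such as the kinase Cdk1 and the topoisomerase Top2a, were higher in G2 than in early G1 as a set, with a median of 0.51 and all 56 members above 0 (camera adjusted p = 1.51e-43). They were also higher than in late G1 (median 0.46; camera adjusted p = 9.15e-37). G1/S and replication genes were higher in late than in early G1 (median 0.23, 38 of 39 above 0; camera adjusted p = 4.49e-16) and lower in G2 than in late G1 (median -0.25; camera adjusted p = 3.69e-18). Replication histones, counted as uncertain single genes, were lower in G2 than in early G1 (median -0.50; camera adjusted p = 5.79e-33) and than in late G1 (median -0.57, 60 of 60 below 0; camera adjusted p = 1.1e-76). With an estimated correlation none of these held: the adjusted p was 0.293 and 0.16 for G2/M genes, 0.398 and 0.16 for G1/S genes, and 0.398 and 0.102 for histones, in the same order. Single genes did not pass: Cdk1 stood at 1.27 ± 0.46 and Top2a at 1.27 ± 0.54 in G2 minus early G1 (edgeR adjusted p = 1; named after their values were seen). The count was 0 in all 3 pairs of phases with edgeR, the replicate block and DESeq2. At an unadjusted p under 0.05 (edgeR without the block) it was 136 for late against early G1, 319 for G2 against early G1 and 174 for G2 against late G1. Each was under 5% of the genes tested, in a fit that leaves out the pairing by replicate number. Adjusted over the list alone, 0 of the 56 G2/M genes passed, and 43 rose in G2 over early G1 with the replicate block.

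Other lists differed between phases with DOX too. Trophoblast, primitive endoderm and formative genes were lower in late than in early G1 (medians -0.29, -0.14 and -0.14; camera adjusted p = 0.00236, 0.00269 and 0.0071) and lower in G2 than in early G1 (medians -0.30, -0.17 and -0.15; camera adjusted p = 0.00943, 0.0241 and 0.0241). With an estimated correlation the adjusted p was 0.484, 0.484 and 0.398, then 0.398, 0.457 and 0.398. With 1 library left out, the 3 late G1 calls held in 4, 4 and 2 of 6 fits and were weakest without early G1 DOX replicate 3 (camera adjusted p = 0.259, 0.15 and 0.15). The 3 G2 calls held in 4, 3 and 2 of 6 fits. They were weakest without G2 DOX replicate 1 for trophoblast (0.323) and without early G1 DOX replicate 3 for primitive endoderm and formative genes (0.289 and 0.266). Intronic G2/M genes were higher in G2 than in early G1 (median 0.24; camera adjusted p = 3.07e-22; adjusted p = 0.424 with an estimated correlation). For introns 0 single genes passed in any pair with edgeR, against 187, 200 and 207 at an unadjusted p under 0.05.

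The third question was how much Esrrb ChIP-seq signal remains in mitosis. Esrrb signal at its 14559 peaks was lower in mitosis than in interphase at 13307 peaks and higher at 7 (limma, adjusted p under 0.05), or 91.4% in all. The higher count was 0 without interphase DOX replicate 4 or mitosis DOX replicate 1 and 2 without mitosis DOX replicate 4. Reads in peaks made up 5.91 ± 2.88% of each library in interphase and 1.21 ± 0.1% in mitosis (SD, n = 4 each; exact permutation p = 0.0286, 2-sided, the smallest that 4 against 4 allows). After withdrawal they made up 0.3 and 0.65% in interphase and 0.31 and 0.71% in mitosis. The difference was uneven. The authors call 1980 peaks Bookmarked (classes 1 to 3) and 12579 Lost (classes 4 and 5), and the median change from class 1 to class 5 was -0.49, -1.79, -1.96, -2.24 and -2.39 log2. Averaged per library, Bookmarked peaks went from 1.94 ± 0.48 to 0.44 ± 0.21 and Lost peaks from 1.57 ± 0.64 to -0.76 ± 0.42 (log2 reads per kb per M; SD, n = 4). Bookmarked peaks exceeded Lost peaks by 0.37 ± 0.19 in interphase and by 1.21 ± 0.53 in mitosis (exact permutation p = 0.0286, 2-sided). Which libraries were used to call the peaks and to set the classes is not given in the sources used here. The share of peaks lower in mitosis and the contrast between categories are therefore not taken as independent evidence. Scaled by TMM on reads in peaks, which removes any general difference between libraries, 7.8% of peaks passed (edgeR). Of these, 774 were higher and 367 lower in mitosis, with 661 of the higher ones Bookmarked. Heights scaled to library totals do not separate a general change in binding from a general difference in ChIP-seq signal between libraries. Within EKOiE alone, 78.3% of peaks passed.

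**Figure D4:**
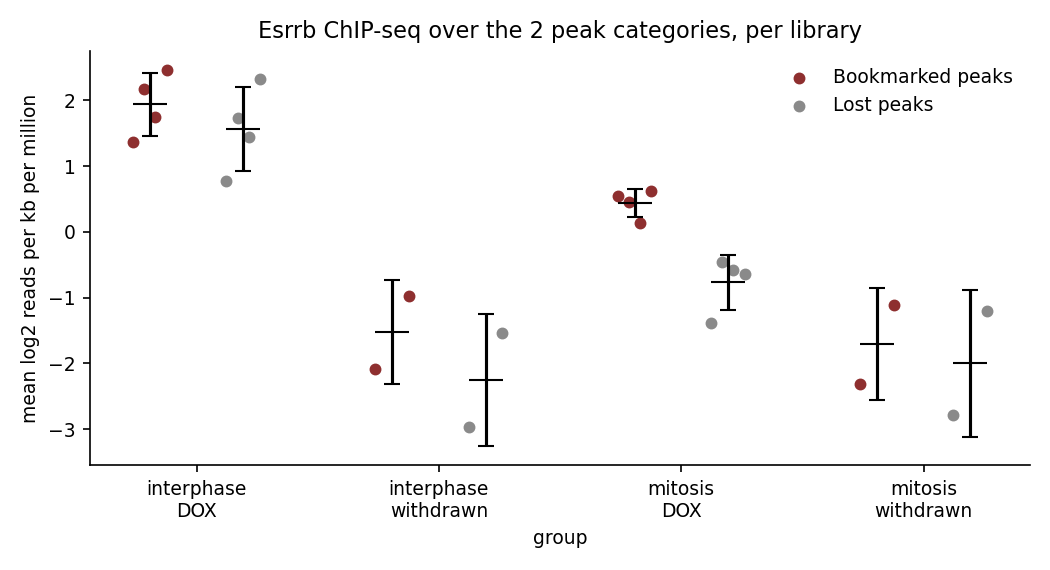
Mean log2 reads per kb per M over Bookmarked and Lost peaks in each ChIP-seq library of the 4 groups; points are libraries and bars the mean and SD (n = 4 with DOX, n = 2 after withdrawal). In mitosis with DOX the Bookmarked peaks average 0.44 and the Lost peaks -0.76, while in interphase they average 1.94 and 1.57.

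The withdrawal libraries served as background for Esrrb antibody signal. In interphase, 14500 of 14559 peaks were higher with DOX than after withdrawal and 0 were lower (limma). How the peaks were called is not given. A choice of peaks in these same libraries would favour this share, so that it is not taken as independent evidence. In mitosis 3256 peaks were higher (22.4%) and 0 lower: 360 of 450 in class 1, 1100 of 1216 in class 2, 168 of 314 in class 3, 1619 of 6621 in class 4 and 9 of 5958 in class 5. Median differences in mitosis for the same classes were 1.85, 2.20, 1.64, 1.48 and 0.95 log2. Which libraries set the classes is not given, so that this order of classes is not taken as independent evidence. The mitotic percentage rested on single libraries: it was 9.3, 13.9 and 6.2 without DOX replicate 2, 3 and 4, 0 without withdrawn replicate 1 and 48.8 without withdrawn replicate 2. DESeq2 called 9.3% and edgeR 0 on reads recovered from the same values. The withdrawal libraries came from EKOiE alone. The mitotic percentage was 4.5 without the E14Tg2a libraries and 8.8 with cell line as a term (limma).

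Peaks beside genes of the naive network give examples, with positions in mm9. In all, 79 peaks lay nearest to 24 of the 29 genes formed by the naive list and Esrrb; all 79 were lower in mitosis, 30 were higher with DOX than after withdrawal in mitosis, and 17, beside 13 genes, were Bookmarked. The Bookmarked peak inside Tfcp2l1 (chromosome 1, 120525151 to 120526350), 1230 bp from its start, was at -1.04 ± 0.44 in mitosis minus interphase (limma adjusted p = 0.0293) and stood 1.69 ± 0.54 above withdrawal there (limma adjusted p = 0.0318). A Bookmarked peak 14012 bp from Zfp42 (chromosome 8, 44405851 to 44406900) was at -2.64 ± 0.49 in mitosis minus interphase (limma adjusted p = 8.07e-05) and at 3.01 ± 0.60 above withdrawal in mitosis (limma adjusted p = 0.00467). Inside Jam2 (chromosome 16, 84778201 to 84781500) the 2 values were -1.94 ± 0.43 (limma adjusted p = 0.000356) and 1.71 ± 0.52 (limma adjusted p = 0.026). Bookmarked peaks nearest to Klf2, Fgf4, Fbxo15 and Spp1 were at -2.72, -2.39, -2.10 and -1.94 and stood 2.42, 2.28, 1.59 and 2.06 above withdrawal in mitosis. Of the 17, 4 did not pass against withdrawal in mitosis: a second peak beside Tfcp2l1 (limma adjusted p = 0.0539), a second beside Zfp42 (0.0795), 1 beside Lifr (0.0662) and that of Zfp57 (0.307). The calls against withdrawal in mitosis depended on the fit. With a pseudocount of 1, and with edgeR on recovered reads (library totals or TMM), 0 of all 1980 Bookmarked peaks passed.

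The 10 highest peaks in mitosis by the authors' pooled height were all Bookmarked and all higher with DOX than after withdrawal in mitosis (limma), which their choice for height in the same mitosis libraries favours. These calls against withdrawal were also absent with a pseudocount of 1 and with edgeR on recovered reads. The highest (chromosome 5, 139449901 to 139451550), 20182 bp from Pdgfa, had a pooled log2 height of 2.27 in mitosis and 3.03 in interphase. Its mitosis minus interphase difference was -1.44 ± 0.56 (limma adjusted p = 0.0198) and its DOX minus withdrawal difference in mitosis 4.90 ± 0.69 (limma adjusted p = 0.000636). The second, inside Capn2, was at -1.58 ± 0.64 (limma adjusted p = 0.0245). For 7 others the change between states did not pass: the peaks nearest to Esp38 (-0.10), Glrx3 (-0.77), Tnik (-0.70), Pcsk5 (1.03), Ntrk2 (-0.95), Lrpprc (-0.47) and Tmx3 (-0.99). The peak nearest to Hs3st5 was higher in mitosis (1.26 ± 0.58; limma adjusted p = 0.043), a call that ended without interphase DOX replicate 4 or mitosis DOX replicate 1, where 0 peaks were higher. Interphase DOX replicate 4 stood far below the other 3 libraries at the peaks of Hs3st5 (-2 against 0.69 to 1.09) and Pcsk5 (-2.27 against 1.43 to 2.12). Of these 10 peaks, those of Esp38, Glrx3, Tnik, Pcsk5, Ntrk2, Tmx3 and Hs3st5 lie over 50 kb from the named gene's start.

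The last question joined both assays: whether genes near Esrrb peaks respond to DOX withdrawal. Each peak counted for its nearest start alone, within 50 kb, so that genes without a peak may lie near a peak assigned to another gene. Genes assigned a Bookmarked peak fell more often than genes without a peak: 4 of 1188 against 3 of 8889 in early G1, 12 against 3 in late G1 and 16 against 26 in G2. The odds ratios were 10 (95% interval 1.69 to 68.3; Fisher's exact p = 0.00501, BH-adjusted 0.0129), 30.2 (p = 2.22e-09) and 4.65 (p = 1.05e-05), each one of 18 tests in the family. Genes beside Lost peaks only fell more often than genes without a peak too, at 10, 24 and 47 of 4015 (odds ratios 7.39, 17.8 and 4.04). The 24 of late G1 include Esrrb itself, the withdrawn gene. Bookmarked against Lost gave odds ratios of 1.35, 1.70 and 1.15 that did not pass (Fisher's exact p = 0.538, 0.161 and 0.65), so that no difference between the categories was shown. Ldhb, Tfcp2l1, Jam2 and Ly6g6e fell in all 3 phases beside a Bookmarked peak, and Wnt7b, Fabp3, Klk1, Csnk1e and Pramel6 in 2 phases; Klk1 has near-identical neighbours and is uncertain as a single gene. Rises were more frequent beside Lost peaks than without a peak in late G1 (odds ratio 3.11; BH-adjusted Fisher's exact p = 0.0152) and G2 (2.42; 0.0106). With peaks within 10 kb neither passed (Fisher's exact p = 0.112 and 0.0593). With replicate-block calls rises were also more frequent beside Bookmarked peaks than without a peak (odds ratios 1.94, 1.56 and 1.64 by phase; BH-adjusted Fisher's exact p = 0.00179, 0.00179 and 0.000111), so that rises are not shown to be particular to Lost peaks. In lists of genes without a peak matched on expression, the median number of falls was 0, 0 and 3 against the 4, 12 and 16 of Bookmarked genes (share of 10000 lists as high = 1e-04, the smallest they can give). As a class, Bookmarked genes moved little: their median exonic changes were -0.011, -0.017 and -0.012 log2 (percentiles 0.02, 0 and 3.83 of these lists). Of these genes, 51.3, 52.6 and 51.5% were below 0. Their intronic medians were 0.006, -0.016 and 0.011 (percentiles 69, 0.02 and 76.6), so that introns were lower in late G1 alone. With replicate-block calls the odds ratios against no peak were 4.96, 2.41 and 2.05, and Bookmarked against Lost in early G1 was 1.37 (Fisher's exact p = 0.0461, BH-adjusted 0.0638).

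**Figure D5:**
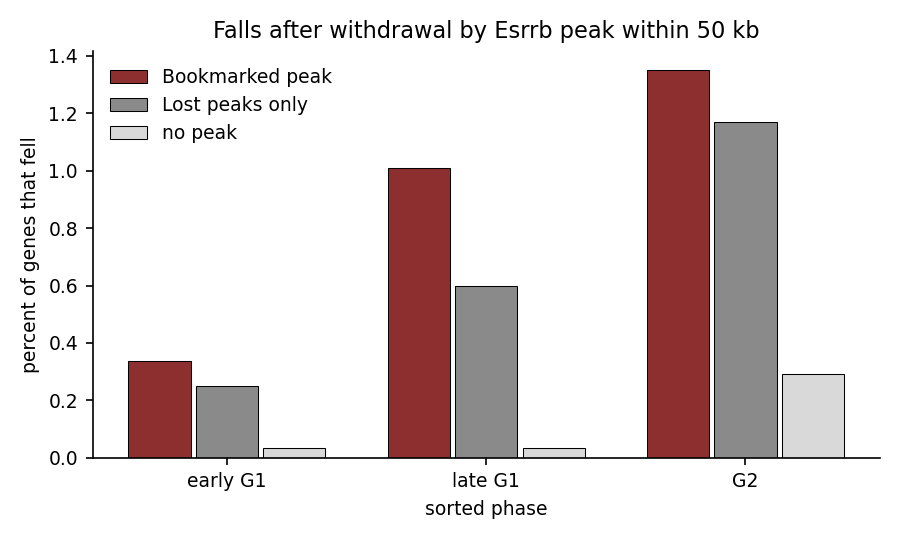
Percent of tested genes that fell after withdrawal (y axis) in each sorted phase (x axis), for genes assigned a Bookmarked peak, Lost peaks only, or no peak. Each peak was assigned to its nearest start within 50 kb, and bars are percentages of 1188, 4015 and 8889 genes. Both peak groups stand above genes with no peak in each phase.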

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

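In this part the ATF4 stress-response list, the test of peak differences between interphase and mitosis and the list tests with the replicate block were chosen after the data were seen. The other tests were planned.

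At a peak nearest to Pcsk5 (chromosome 19, start 17800051, mm9), interphase DOX replicate 4 had a log2 height of -2.27, while the other 3 interphase libraries lay between 1.43 and 2.12 (gap over range 0.843). At a peak nearest to Hs3st5 (chromosome 10, start 35835751), the same library stood at -2 against 0.69 to 1.09 (0.871). These were 2 of 64 groups of 4 libraries checked, and chance puts about 1 in 20 groups this far apart. No explanation was tested for them. That library has the fewest reads of the interphase DOX group, 10.7 M.

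For 7 results the withdrawal response of a gene list differed between phases with camera at its preset correlation, and none held with an estimated correlation. Trophoblast genes responded lower in late than in early G1 (median of the members' differences in response -0.25; camera adjusted p = 0.018, and adjusted p = 0.994 with an estimated correlation) and lower in G2 than in early G1 (-0.44; camera adjusted p = 0.0015, and adjusted p = 0.863 with an estimated correlation). G2/M genes responded lower in late than in early G1 (-0.05; camera adjusted p = 0.0303, and adjusted p = 0.994 with an estimated correlation). In introns their response was lower in G2 than in late G1 (-0.11; camera adjusted p = 0.0236, and adjusted p = 0.898 with an estimated correlation). Replication histones responded lower in late than in early G1 (-0.16; camera adjusted p = 0.00584, and adjusted p = 0.994 with an estimated correlation). ATF4 stress-response genes responded higher in G2 than in early G1 (0.07; camera adjusted p = 0.0234, and adjusted p = 0.439 with an estimated correlation) and than in late G1 (0.11; camera adjusted p = 0.000538, and adjusted p = 0.245 with an estimated correlation). With the replicate block the same 7 passed at camera's preset correlation, at adjusted p between 0.000148 and 0.0356.

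At 5459 of 14559 peaks the difference between DOX and withdrawal was smaller in mitosis than in interphase, and at 1 it was larger (limma, BH-adjusted p under 0.05). The median difference of differences by class was -0.19, -1.6, -1.94, -2.32 and -2.8 log2 for classes 1 to 5. How the peaks were called and which libraries set the classes is not given, so that neither these counts nor this order is taken as independent evidence.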

How the results depend on the processing

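Summed phases, fits of recovered peak reads and the cell-line term were added after the data were seen. So were list tests with the block, comparisons of genes beside peaks with block calls, and left-out libraries for the exonic and intronic correlation. Apart from named genes, 162 values under other settings kept their direction and side of the threshold (counts within 1.5-fold), 37 moved, 2 passed newly and 0 reversed. With 1 library left out 150 kept them, 47 moved and 0 reversed. Counts of 0 that stayed at 0 are among those kept in both tallies. All phase differences and differences in response are of this kind, so that the tallies do not measure stability. The 68 named gene and phase pairs all stayed past the threshold with the replicate block, DESeq2 and RLE factors; 56 did with library totals alone, 62 without a filter, 67 with the stricter filter and 21 with the compared groups alone. With 1 library left out they stayed so in 176 fits and did not in 232. The cause of the changes below was not tested, except that groups alone and left-out libraries leave fewer samples.

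In exons, the early G1 count of 23 became 14 without a filter, 568 with the replicate block, 129 with DESeq2 and 6 with the groups alone. The late G1 count of 65 became 1274 with the block, 332 with DESeq2 and 2 with the groups alone, and the G2 count of 137 became 1580, 449 and 25 in the same order. Counts of the summed phases, 23 in edgeR, were 1734 with the block, 68 without a filter and 523 with DESeq2. In introns, early G1 had 0 calls, 67 with the block and 13 with DESeq2. Late G1 had 2, with 89 and 15, and 0 with library totals and with the groups alone. G2 had 2, with 228 and 41, 1 with library totals and 0 with the groups alone. The summed introns had 0 calls in edgeR, 1007 genes at an unadjusted p under 0.05, 521 with the block and 69 with DESeq2.

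Leaving out 1 library gave 4 to 16 exonic calls in early G1 (4 to 7 among those over 1.5-fold away), 11 to 38 in late G1, 21 to 157 in G2 (21 to 85 in the same sense) and 1 to 9 for the summed phases. For the sums the counts were 8, 1 and 7 without DOX replicate 1, 2 and 3 and 9, 2 and 6 without withdrawn replicate 1, 2 and 3. Intronic counts ran from 0 to 2 in late G1, 0 to 4 in G2 and 0 to 1 for the summed phases. The correlation of exonic with intronic changes ran from 0.27 to 0.41 in early G1, 0.31 to 0.49 in late G1 and 0.24 to 0.44 in G2. Phase differences and differences in response stayed at 0 calls in every setting.

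For peaks, the share that differed between mitosis and interphase (91.4%) was 7.8% with TMM and 79 to 92.9% with 1 library left out, and 78.3% without E14Tg2a. The share higher with DOX in interphase (99.6%) was 0 with TMM and 93.8 to 99.9% with 1 library left out. The same share in mitosis (22.4%) was 36.8% with the replicate block, 42.4% in the higher part of the peaks, 0 with a pseudocount of 1, 9.3% with DESeq2, 0 with edgeR at library totals and with TMM, 8.8% with cell line as a term, 4.5% without E14Tg2a and 0 to 48.8% with 1 library left out. ChIP-seq replicate numbers did not pair the libraries: same-numbered deviations correlated at 0.47, -0.31, 0.24 and 0.12. Their block gave 96.4% for mitosis against interphase, and a DOX minus withdrawal difference smaller in mitosis at 12431 peaks and larger at 11 (5459 and 1 without it).

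Of 228 list tests, 49 passed with camera's preset correlation, 3 with an estimated one, 10 with fry, 58 with the block and 7 with the block and an estimated correlation. Bookmarked against Lost genes reached Fisher's exact p = 0.0461 in early G1 with block calls (odds ratio 1.37) and 0.0164 in introns in late G1 (2.2) for falls. For rises it reached 0.0446 in early G1 (1.52) and 0.0498 in G2 (1.28) with block calls, and the other way 0.0412 in G2 with peaks at any distance (0.305). With unblocked intronic calls the ratios of Bookmarked genes to genes without a peak had no finite value, since the latter had 0 falls in every phase, and in early G1 the ratio to Lost genes had none either. At a threshold of 0.01 the ratio to genes without a peak had none in early and late G1. The block changed these further list calls at camera's preset correlation: for phases with DOX, 2-cell-like genes passed in G2 minus early G1 (adjusted p = 0.0312), and naive, immediate-early and glycolysis genes in G2 minus late G1 (0.00955, 0.036 and 0.0386). For differences in response, neural, 2-cell-like and ATF4 genes passed in late against early G1 (0.0356, 0.0113 and 0.0405), and core pluripotency and 2-cell-like genes in G2 against early G1 (0.00328 and 0.04). In introns, fibroblast genes were lost in late minus early G1 (0.0416 to 0.212), ATF4 genes passed in G2 minus late G1 (0.0419), and 2-cell-like and G2/M genes in the response of G2 against early G1 (0.0372 and 0.0467). None of the calls gained here held with an estimated correlation as well (adjusted p = 0.351 to 0.906). Other calls of lists did not change with it, apart from those in the report.

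Few small changes pass: 17.9% of simulated 1.5-fold changes were recovered in early G1, in libraries simulated without an effect shared by replicate number. Depth was not varied. Same-group exonic libraries differed by a chi-square per gene of 11.13 to 65.44, where counting error alone gives about 1. Separate samples can exceed that value at any depth, so that this does not decide whether depth limits recovery. For peaks, the mitosis libraries with DOX held medians of 25, 46, 31 and 22 reads per peak. The background library of mitosis withdrawal replicate 1 held a median of 2.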

Other observations

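Of the tests below, the G2/M test of the sorts, the ATF4 list, the counts for other splits and the genes named in the first paragraph were chosen after the data were seen. So were list results and comparisons of genes beside peaks that use the replicate block. The other tests were planned.

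Several genes passed with the replicate block and not without it; the log2 changes, SE and adjusted p of the genes up to Dppa2 are those of the blocked fit. Dnmt3b, a de novo DNA methyltransferase, was at 0.66 ± 0.14, 0.77 ± 0.14 and 0.84 ± 0.14 in early G1, late G1 and G2 (edgeR adjusted p = 0.0122, 0.00299 and 0.00132). Its cofactor Dnmt3l was at 0.64, 0.67 and 0.80 (edgeR adjusted p = 0.00325, 0.00148 and 0.000295). The Wnt effector Lef1 was at 1.59 ± 0.35, 1.59 ± 0.35 and 2.18 ± 0.33 (0.0158, 0.0101 and 0.000699). Zic2 and Zic5 passed in late G1 and G2, at 0.76 and 0.76 for Zic2 (0.0225 and 0.0218) and 0.80 and 0.88 for Zic5 (0.0286 and 0.014). On the other side, the naive factor Tbx3 was at -0.64, -0.66 and -0.59 (edgeR adjusted p = 0.0167, 0.00959 and 0.0128) and the STAT3 target Pim3 at -0.51, -0.51 and -0.42 (0.00434, 0.00303 and 0.00738). Gata6, a primitive endoderm factor, was at -1.38 ± 0.42 in late G1 and -1.58 ± 0.38 in G2 (0.0471 and 0.0134). Nanog stood at -0.32 ± 0.10 in G2 (0.0379), and Dppa2, another naive gene, at 0.35 in late G1 and 0.46 in G2 (0.0193 and 0.00378). None of these genes passed without the block in the phases given. Klk1 and its near-identical neighbours Klk1b4, Klk1b5 and Klk1b9, kallikreins whose copies are uncertain as single genes, fell together in G2 without the block (edgeR adjusted p = 0.0101, 0.0245, 0.0332 and 0.0201). With the block 994 genes fell in at least 1 phase and 1051 rose.

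Further lists differed between phases with DOX, by camera at its preset correlation and by none with an estimated one. In late minus early G1 they were 2-cell-like genes (median -0.30; adjusted p = 0.0123), fibroblast and feeder markers (-0.33; 0.0231), G2/M genes (0.07; 0.00158), ERR and oxidative genes (0.08; 0.00117), replication histones (0.15; 3.38e-05) and ATF4 genes (0.12; 0.0026). Their adjusted p with an estimated correlation was 0.645, 0.527, 0.842, 0.586, 0.802 and 0.308 in that order. In G2 minus early G1 they were naive genes (0.10; 0.0241), ERR and oxidative genes (0.06; 0.0241), p53 targets (-0.10; 0.0418) and ATF4 genes (0.14; 0.00297), with 0.656, 0.656, 0.398 and 0.315 with an estimated correlation. With 1 library left out, the calls in late minus early G1 held in 2, 4, 4, 4 and 5 of 6 fits in that order (highest adjusted p = 0.84, 0.25, 0.753, 0.337 and 0.649) and those in G2 minus early G1 in 3, 3 and 2 (0.527, 0.489 and 0.379), apart from ATF4 genes, for which this was not run. In introns, withdrawal calls were also met for naive genes in early G1 and G2 (medians -0.11 and -0.09; camera adjusted p = 0.0049 and 0.0464), formative genes in early G1 (0.19; 0.0355) and G2/M genes in early G1 and G2 (-0.08 and -0.19; 0.0479 and 7.92e-05). They held in 4, 2, 2, 3 and 5 of 6 fits, and none with an estimated correlation (adjusted p = 0.277 to 0.851).

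The first pattern is that 0 single genes passed between sorted phases with DOX (edgeR), and 0 with DESeq2. At an unadjusted p under 0.05 the counts without the block were 136, 319 and 174, under the 5% of 14092 genes that chance gives. They are not taken as a sign of weaker differences. The fit leaves out the pairing by replicate number, so that these counts do not decide whether phases differ. Sorts that were mixed up or not separated would leave no shift in G2/M genes, but their median was 0.51 log2 higher in G2 than in early G1, with all 56 members above 0. That argues against a complete mix-up, although the list's call had an adjusted p of 0.293 with an estimated correlation. Differences too small for the test stay open and may account for part of the pattern: 14.9% of simulated 1.5-fold changes were recovered in this contrast, but 65.7% at 2-fold and 90.9% at 4-fold. They are not shown to cover Cdk1 and Top2a, at 1.27 log2 each, or the 43 of 56 G2/M genes that passed over the list alone with the replicate block. Unlike the real libraries, the simulated ones shared no effect by replicate number, so that the recovered shares may not hold here. Partly overlapping sort gates stay open too, as untested.

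The second pattern is the rise in exonic withdrawal calls with the replicate block, from 225 to 3422 summed over the 3 phases. A loss of degrees of freedom or an effect of any block is argued against: in 20 random renumberings within groups the median was 171 calls, with a lowest of 84. A shared culture day or batch of same-numbered libraries remains a candidate explanation, since the highest renumbering gave 498 calls, under the real 3422. The labels name no batch, so that day, batch and sort cannot be separated.

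The third comparison is of falls beside Bookmarked and Lost peaks, where the odds ratios of 1.35, 1.70 and 1.15 did not pass and were 1.37, 1.02 and 0.9 with block calls, so that no pattern is established. Higher interphase binding of Bookmarked peaks may account for the ratios above 1: among 10000 lists of Lost genes matched on that height, the Bookmarked falls reached at most the 91.4th percentile, in late G1, and 56.2 and 22.3 in early G1 and G2. Higher expression stays open, with percentiles of 67, 98.4 and 75.6 among expression-matched lists: the bound of 95 set against it named no phase, was passed in late G1 alone, and with block calls in early G1 alone (99.3, 53.4 and 25.8). With block calls the height-matched percentiles were 98.2, 23.7 and 0.73. A role of retention in mitosis stays open.

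A further hypothesis is that doxycycline itself raises the ATF4 stress response in the DOX cells, which may add to the withdrawal changes; 28 ATF4 stress-response genes were tested for it. Its exonic medians on withdrawal were 0, -0.05 and 0.09 (camera adjusted p = 0.425, 0.107 and 0.511), with members on both sides, which decides nothing. In introns the medians were -0.07, -0.13 and -0.15 (camera adjusted p = 0.0176, 0.00483 and 0.00129; adjusted p = 0.343, 0.263 and 0.208 with an estimated correlation).

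Other splits of the same libraries were counted for each fit. The 10 splits of 3 against 3 are too few for a share under 0.05. The exonic withdrawal counts of 23, 65 and 137 and the summed count of 23 were each reached by 1 split, the real one, and the highest other gave 0, also among the 4 splits that part all same-numbered pairs. The same held for the intronic counts of 2 in late G1 and 2 in G2. The intronic early G1 and summed counts and all pairs of phases were 0 in the real and in all 10 splits. At an unadjusted p under 0.05, other splits gave up to 1925, 2293 and 1231 genes in early G1, late G1 and G2, against 1357, 1847 and 2034. For late minus early G1, G2 minus early G1 and G2 minus late G1 with DOX they gave up to 1647, 2512 and 1804, against 136, 319 and 174, and 7, 7 and 5 of 10 were as large. In introns the highest others were 1013, 2077 and 1754 for withdrawal, against 806, 820 and 1084, and 801, 1304 and 1095 for pairs of phases, against 187, 200 and 207. For differences in response, regroupings gave up to 4215, 3687 and 1423 exonic genes, against 36, 64 and 72, and 20, 18 and 21 of 21 were as large. Splits several times above the real count point to a structure of the libraries other than phase. Differences in response were 0 in the real and in the other regroupings, 21 of 21, which a count of 0 gives by construction, so that chance is not excluded and the comparison decides nothing. For mitosis against interphase 13314 peaks passed in the real split, 1 of 35, and 0 in the highest other. That share is under 0.05 and the smallest these splits allow. Peaks of a library can move together, so that chance is unlikely but not excluded. How the peaks were called is not given, and their choice may favour the real split.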
